A study of Mus musculus with 9 samples.

How the data were processed

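Total RNA of 9 mouse cell cultures had been labelled with biotin and hybridised to a single-colour Affymetrix array, 1 array per culture. The deposited values were log2 signals per probe set, normalized between arrays by the authors, who stated neither the method nor the base of the logarithm. The base was inferred from the range of the values, with array minima from 2.15 to 2.29 and maxima from 13.7 to 14.0. The medians of the arrays lay between 6.49 and 6.56. The labels named limma as the authors' tool, without a version. The lines were assigned to ESC, TSC, Cdx2, miR-15b, miR-322 and miR-467g by their sample labels, which gave 3 groups of 1 array and 3 groups of 2 arrays. RNA had been extracted by one of 2 methods, and which one was not stated per sample.

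Of 35556 probe sets, 21789 carried 1 gene symbol, 1621 several and 12146 none. A gene was represented by its single-symbol probe set with the highest mean over all arrays, which concerned 999 genes with several probe sets and left 19938 genes. No filter on signal was applied. The label check of the microRNA genes used all 23410 probe sets with a symbol, since the Mir322 probe set carries several.

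All 9 arrays were fitted together in limma 3.58.1 with R 4.3.3, with a mean per group and no covariate. The spread therefore came from the 3 pairs of microRNA lines (3 residual degrees of freedom, 2.19 prior degrees of freedom, prior SD 0.128), and the lone ESC, TSC and Cdx2 arrays were assumed to vary as these pairs did. Given errors are SE of the difference from this fit. There were 10 comparisons, each of 2 groups or of averages in which every microRNA had equal weight, and an F test among the 3 microRNAs. Genes were called at a Benjamini-Hochberg adjusted two-sided p under 0.05 over all genes. The 27 gene lists with at least 3 measured members had been written before the data were examined. They were tested with camera at an inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the residuals. Beside each list, its members were also adjusted over the list alone.

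Named genes followed a rule written before the data were examined. It took the 8 largest rises and 8 largest falls per comparison among called genes for which both lines of a pair moved alike, a fixed set of lineage regulators, up to 4 members per list with the largest differences, and the genes the lines were built to express. Gene models, small RNAs and receptor families were left out of the first part, and the pattern for small RNAs was widened to Y RNAs after the values were seen. Lum in TSC against ESC, Fn1 and the limb genes were named outside the rule, after their values were seen, and Cdh1 as an example of its list. The regulator T was not among the tested genes.

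Position between ESC and TSC was the slope of an array's difference from ESC on that of TSC through the origin, over called genes with an absolute log2 difference of 2 or more. A gene counted as moved at 1 log2 unit toward TSC. The part of the covariance owed to the shared ESC array was taken from 100 simulations in which the groups did not differ, and the overlap of calls from 100 further ones with all 9 arrays fitted as the data were. Slopes of unchanged lines came from 100 more, with noise of the moderated spread of each gene. Likeness of lines was the mean Pearson correlation of same-microRNA lines after removal of the mean of the 6 lines per gene, with a one-sided exact permutation test over the 15 ways to pair 6 lines. Relations between list means over the 6 microRNA lines used two-sided exact permutation tests over 720 orders, adjusted over 26 relations. Figures were drawn with matplotlib 3.10.9.

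The fit was tested on simulated data with known changes and the design of the 9 arrays. For the microRNA average against ESC, 31.3% of genes changed by 1 log2 unit were recovered, 71.6% of those changed by 2 and 93.9% of those changed by 4, with 2 false calls. For TSC against ESC these were 16.4%, 64.2% and 83.3%, with 7 false calls, and for the lines labelled miR-467g against the others 49.3%, 80.6% and 97%, with 8 false calls. The simulated noise was independent between genes and arrays, and the lone arrays were given the spread of the pairs. In the data many genes differed together between lines, so recovery and false calls on the real arrays can differ from these figures.

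The alternatives tried were quantile normalization, median centring, a filter on dim genes, the mean of all probe sets of a gene, limma with trend and robust options, a log2 limit with and without a test, fits of only the groups compared, the 6 microRNA lines as 1 group, camera with an estimated correlation, other gene sets for the axis, Spearman correlation and leaving out each line in turn. Added after the data were seen were the mean of the fibroblast feeder list as a covariate, the removal of the first miR-322 line with the second line labelled miR-467g, and the removal of both lines labelled miR-467g. A planned test of seed matches in transcripts was not run, because no transcript sequences were available.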

Results

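Gene expression was profiled in mouse cells on 9 single-colour Affymetrix arrays, each hybridised with total RNA of 1 culture. The R1 embryonic stem cell (ESC) line and the F4 trophoblast stem cell (TSC) line, each on 1 array, stood for the starting fate and the target fate. ESC are derived from the inner cell mass and give rise to the embryo proper, whereas TSC are derived from the trophectoderm and give rise to the placenta. A further array held an R1 derivative with inducible Cdx2, the transcription factor that specifies trophectoderm. The other 6 arrays held clonally derived R1 lines with an inducible microRNA, 2 lines each for miR-15b, miR-322 and miR-467g, which are microRNAs enriched in TSC. The induced lines were grown on feeder fibroblasts in TSC medium with FGF4, heparin and doxycycline, and valproic acid, a histone deacetylase inhibitor, was added a day later. The labels gave 6 days of induction in one field and 10 days of culture in another. The ESC were grown on feeders in medium with LIF and without these additions, so that medium, drugs and transgene could not be separated in comparisons with ESC. Changes are given as log2 differences with the standard error (SE) from the fit across all genes. The ESC, TSC and Cdx2 groups had n = 1 and each microRNA had n = 2, so the number of arrays limited the precision.

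The microRNA genes themselves were examined first, because the precursor of an induced microRNA can be seen on such an array. The Mir15b probe set had log2 signals of 10.73 and 11.52 in the miR-15b lines and lay between 3.59 and 5.04 on the other 7 arrays. Its difference from ESC was 7.04 (SE 0.65, adjusted p = 0.00864 over 23410 probe sets with gene symbols). The Mir322 probe set, which is shared with the host transcript of that microRNA, had signals of 7.66 and 10.85 in the lines labelled miR-322. It had a signal of 11.78 in both lines labelled miR-467g, which was 7.56 above ESC (SE 1.32, adjusted p = 0.0289). In the lines labelled miR-322 the difference from ESC was 5.03 (SE 1.32, adjusted p = 0.0708), which did not pass. Nor did the difference of 2.52 between the lines labelled miR-467g and miR-322 (SE 1.08, adjusted p = 1) or the F test of this probe set (adjusted p = 0.650). No probe set was specific to miR-467g, and the probe sets shared within its family had mean signals between 2.68 and 4.66 over the 9 arrays. The expression of miR-467g in the lines that carry its name therefore could not be read from these arrays, and these lines are called the lines labelled miR-467g throughout.

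**Figure D1:**
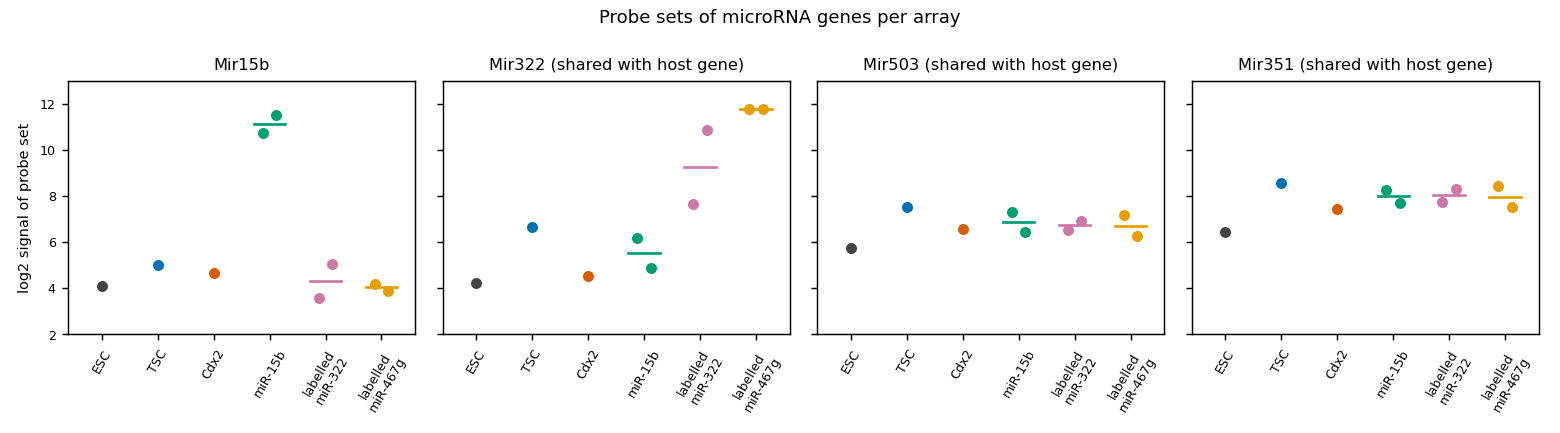
Log2 signal (vertical axis) of the probe sets of Mir15b, Mir322, Mir503 and Mir351 on each array (points), with bars at the means of pairs of lines and groups along the horizontal axis. Mir15b was at 10.73 and 11.52 in the miR-15b lines, and the Mir322 probe set was at 11.78 in both lines labelled miR-467g.

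The TSC and ESC arrays, which served as references of the 2 fates, differed in the genes that define each cell type. Elf5, a transcription factor that maintains trophoblast identity, was 67.3-fold higher in TSC (log2 6.07, SE 0.42, adjusted p = 0.00453). Eomes and Gata3, transcription factors of early trophoblast, were higher by 5.24 (SE 0.51) and 4.66 (SE 0.50), and Cdx2 was higher by 3.72 (SE 0.62). The calls of Gata3 and Cdx2 held in only 4 and 2 of the 6 fits that left out a line. Pou5f1, which encodes the pluripotency factor OCT4, was lower in TSC, with a difference of -7.05 (SE 0.28, adjusted p = 0.00131), and Nanog was 32.1-fold lower (adjusted p = 0.00453). Sox2 and Esrrb, which serve both stem cell types, had differences of -0.48 (SE 0.51) and -0.66 (SE 0.73) that did not pass.

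Of 19938 genes tested with limma, 863 were higher and 690 lower in TSC. Among 18 measured TSC core factors, 11 rose and 0 fell. Adjusted over the list alone, 16 rose. The list as a whole was higher (median 3.23, camera adjusted p = 3.37e-11; adjusted p = 0.645 with an estimated correlation). Differentiated trophoblast genes were higher as a list (camera adjusted p = 1.03e-05; adjusted p = 0.454 with an estimated correlation), with 5 of 21 members up and 8 adjusted over the list alone. They included Hand1 (5.09, SE 0.86), a regulator of giant cells, and the placental hormone genes Prl7a1 (4.78, SE 0.18) and Prl2a1 (3.60, SE 0.16). Of 27 pluripotency genes 15 fell and 0 rose, with 17 falling when adjusted over the list alone (median -2.64, camera adjusted p = 1.26e-15; adjusted p = 0.454 with an estimated correlation). Tdgf1 (-6.93, SE 0.20), Nr0b1 (-6.10, SE 0.18) and Lefty2 (-6.14, SE 0.17) showed the largest of these falls that passed, besides Pou5f1.

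Epithelial junction genes were also higher in TSC, and 4 of 15 rose (5 adjusted over the list alone), as the list did (camera adjusted p = 0.000777; adjusted p = 0.713 with an estimated correlation). The keratin genes Krt19 (4.55, SE 0.71), Krt18 (4.29, SE 0.65) and Krt8 (4.07, SE 0.55) were among them and belong to the TSC core list as well. Their calls, like that of Hand1, held in only 2 of the 6 fits that left out a line. Germline genes were lower, with 3 of 18 members passing (4 adjusted over the list alone; camera adjusted p = 0.000599; adjusted p = 0.645 with an estimated correlation), including the meiotic gene Hormad1 (-2.10, SE 0.26). Two-cell-like genes, which mark a rare ESC state, were lower with 2 of 6 passing (4 adjusted over the list alone; camera adjusted p = 0.0363; adjusted p = 0.713 with an estimated correlation). The fibroblast feeder list was lower in TSC, with a median of -1.11 (camera adjusted p = 1.87e-06; adjusted p = 0.713 with an estimated correlation). Of its 24 genes 1 passed, the matrix gene Lum, and 7 adjusted over the list alone. Whether the TSC were grown on or off feeders was not stated. The count of 1553 genes fell to 370 without either miR-322 line, since the spread came only from the pairs of microRNA lines.

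In the Cdx2 line, several trophoblast regulators were high after induction, as the positive control for trophoblast fate in this design. Cdx2 was 11.5-fold higher than in ESC (log2 3.52, SE 0.62, adjusted p = 0.0473), and Elf5 and Eomes were higher by 4.41 (SE 0.42) and 4.22 (SE 0.51). The keratin genes Krt8 (4.24, SE 0.55), Krt18 (4.44, SE 0.65) and Krt19 (4.75, SE 0.71) and the homeobox gene Rhox9 (4.61, SE 0.69) were also higher. Pou5f1 and Nanog were lower, with differences of -3.62 (SE 0.28) and -3.35 (SE 0.35). Gata3 (2.50, SE 0.50, adjusted p = 0.0622) and Hand1 (3.97, SE 0.86, adjusted p = 0.0721) did not pass.

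With limma, 388 genes were higher and 532 lower in the Cdx2 line than in ESC. Of the TSC core factors 6 of 18 rose, and 10 when adjusted over the list alone (median 1.93, camera adjusted p = 3.95e-05; adjusted p = 0.569 with an estimated correlation). Of the pluripotency genes 12 of 27 fell, and 18 when adjusted over the list alone (median -2.32, camera adjusted p = 1.19e-18; adjusted p = 0.463 with an estimated correlation), with Lefty1 (-5.53, SE 0.19), Tdgf1 (-5.20, SE 0.20) and Nr0b1 (-4.75, SE 0.18) among them. Formative and primed epiblast genes fell in 4 of 12 cases (7 adjusted over the list alone), including Otx2 (-4.11, SE 0.16) and Zic5 (-2.26, SE 0.29), and the list was lower (camera adjusted p = 0.000333; adjusted p = 0.545 with an estimated correlation). Epithelial junction genes were higher (3 of 15 rose, 4 adjusted over the list alone; camera adjusted p = 0.000432; adjusted p = 0.691 with an estimated correlation), and the 3 were keratins of the TSC core list.

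Genes of the DNA methylation machinery were lower in the Cdx2 line as a list (camera adjusted p = 0.0166; adjusted p = 0.569 with an estimated correlation), where 1 of 8 passed (3 adjusted over the list alone), namely the demethylase gene Tet2 (-2.13, SE 0.24). Differentiated trophoblast genes were not called, and 0 of 21 passed with limma either over all genes or adjusted over the list alone. The fibroblast feeder list was lower with a median of -0.66 (camera adjusted p = 0.000779; adjusted p = 0.719 with an estimated correlation), although 0 of 24 genes passed with limma (2 adjusted over the list alone). In this comparison 4567 genes had an unadjusted p under 0.05. The count of 920 genes fell to 24 without either miR-322 line, 0 higher in limma and 24 lower, and to 26 without either miR-15b line. Cdx2, Elf5, Eomes, Krt8, Krt18, Krt19, Rhox9, Pou5f1, Nanog, Zic5 and Tet2 passed in only 2 of the 6 fits that left out a line. Lefty1, Tdgf1, Nr0b1 and Otx2 passed in all 6.

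The microRNA lines shared a fall of pluripotency genes and a rise of the keratin genes Krt8, Krt18 and Krt19 relative to ESC, and had no called rise of Cdx2, Eomes or Elf5. On average over the 3 microRNAs, Nr0b1, a nuclear receptor of naive pluripotency, had a difference of -7.42 (SE 0.14, adjusted p = 0.000295), and Pou5f1, Nanog and Sox2 had differences of -6.07 (SE 0.21), -5.24 (SE 0.26) and -4.70 (SE 0.39). Krt18 and Krt8 were 21.6-fold and 18.6-fold higher (log2 4.43, SE 0.50, and 4.22, SE 0.42). In this average both passed in all 6 fits that left out a line, and Krt19 in 4. By microRNA, Krt19 passed in only 2 of the 6 fits each. Krt18 passed in 4 for miR-15b, 2 for miR-322 and 4 for the lines labelled miR-467g. Hand1 was higher by 3.82 (SE 0.66, adjusted p = 0.0226) and Gata3 by 2.50 (SE 0.39, adjusted p = 0.0170), which passed in 2 and 4 of the 6 fits that left out a line. Cdx2 (0.92, SE 0.47, adjusted p = 0.268), Eomes (1.06, SE 0.39, adjusted p = 0.143) and Elf5 (0.89, SE 0.32, adjusted p = 0.134) did not pass.

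With limma, 1687 genes were higher and 1484 lower in this average. TSC core factors were higher as a list (median 1.03, camera adjusted p = 3.12e-05; adjusted p = 0.499 with an estimated correlation), and 7 of 18 rose both over all genes and when adjusted over the list alone. The 4 largest were keratins, Krt18, Krt8, Krt7 (4.21, SE 0.77) and Krt19 (3.73, SE 0.54), which mark simple epithelia as well as trophoblast. Of the 27 pluripotency genes 19 fell and 0 rose (23 adjusted over the list alone; median -3.23, camera adjusted p = 4.85e-22; adjusted p = 0.367 with an estimated correlation). Formative and primed epiblast genes fell in 7 of 12 cases, also when adjusted over the list alone (camera adjusted p = 3.12e-05; adjusted p = 0.417 with an estimated correlation), including Otx2 (-4.24, SE 0.12), Zic5 (-4.10, SE 0.22) and Zic2 (-3.33, SE 0.29). Differentiated trophoblast genes were not called as a list (camera adjusted p = 0.121), but 4 of 21 rose, over all genes and adjusted over the list alone, among them Plac1 (3.54, SE 0.82), a placental surface gene that passed for none of the microRNAs alone, and the prostaglandin transporter gene Slco2a1 (1.77, SE 0.25).

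Genes of the p53 response were higher in the microRNA lines than in ESC, and 6 of 10 rose (7 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.00551; adjusted p = 0.499 with an estimated correlation). Examples were Perp (2.63, SE 0.14), Btg2 (1.95, SE 0.20), Phlda3 (1.64, SE 0.18) and Mdm2 (1.07, SE 0.17), the last encoding the ubiquitin ligase of p53. Perp and Btg2 were also called higher in TSC than in ESC (2.06 and 1.29), and Perp and Phlda3 in the Cdx2 line (1.86 and 1.38). In the Cdx2 line Btg2 (1.32) and Mdm2 (0.53) did not pass, and the list was called in neither comparison. Cell cycle genes were lower as a list (median -1.61, camera adjusted p = 3.12e-05; adjusted p = 0.636 with an estimated correlation), with 2 of 19 passing over all genes and 0 with limma when adjusted over the list alone. This list too fell as the fibroblast feeder list rose over the 6 lines (r = -0.961). With the fibroblast list as covariate, chosen after the data were seen, the cell cycle list was still lower than in ESC (camera adjusted p = 2.92e-14). Its means were 8.21 and 8.16 in the first miR-322 line and the second line labelled miR-467g, between 9.34 and 9.99 in the other 4 lines, and 10.70 in ESC. The other 4 lines thus also lay below ESC, by less than those 2 lines did. A fit without those 2 lines keeps only 1 pair of lines to give the spread. The DNA methylation machinery was lower (3 of 8 fell, and 5 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.00476; adjusted p = 0.499 with an estimated correlation), led by the demethylase genes Tet1 (-4.49, SE 0.41) and Tet2 (-1.98, SE 0.18). Over the 6 lines this list fell as the fibroblast feeder list rose (r = -0.997). The DNA methylation means were 7.86 and 7.84 in the first miR-322 line and the second line labelled miR-467g. The other 4 lines had 8.45 to 9.19, and ESC had 10.00. Hippo and YAP targets were higher, with 3 of 8 rising over all genes and adjusted over the list alone, namely Crim1 (1.28, SE 0.24), Ccn1 (1.17, SE 0.16) and Amotl2 (1.07, SE 0.19), and a camera adjusted p of 0.0497 (adjusted p = 0.499 with an estimated correlation). They rose with the fibroblast feeder list (r = 0.987), with the highest means, 10.65 and 10.57, in the same 2 lines. The other 4 lines had 9.99 to 10.32, and ESC had 9.59.

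Immune genes had the same camera adjusted p of 0.0497 (adjusted p = 0.499 with an estimated correlation), and the 2 of 10 that rose, over all genes and adjusted over the list alone, were Lyz2 (2.11, SE 0.40), a lysozyme gene of macrophages, and Csf1r (1.41, SE 0.13), a receptor of macrophages and trophoblast. Two-cell-like genes (2 of 6 fell, 4 adjusted over the list alone; camera adjusted p = 0.0120; adjusted p = 0.520 with an estimated correlation) and germline genes (1 of 18 fell, also adjusted over the list alone; camera adjusted p = 0.0497; adjusted p = 0.636 with an estimated correlation) were lower. Over the 6 lines germline genes fell as the fibroblast feeder list rose (r = -0.951). Their means were 5.79 and 5.78 in the first miR-322 line and the second line labelled miR-467g. The other 4 lines had 6.34 to 6.92, and ESC had 6.68. Ribosomal protein genes were lower by a median of -0.16 with 4 of 57 falling, also adjusted over the list alone, such as Rpl12 (-0.86, SE 0.12), and their camera adjusted p was 6.52e-05 (adjusted p = 0.499 with an estimated correlation). They too fell as the fibroblast feeder list rose (r = -0.974). Their lowest means, 10.80 and 10.79, were in the first miR-322 line and the second line labelled miR-467g. The other 4 lines had 10.90 to 11.05, and ESC had 11.14. Hox genes were higher (median 0.54, camera adjusted p = 0.00476; adjusted p = 0.636 with an estimated correlation). Over all genes 1 of 37 rose, and 0 with limma when adjusted over the list alone. Over the 6 lines the Hox list rose with the fibroblast feeder list (r = 0.991), with means of 7.28 and 7.34 in the first miR-322 line and the second line labelled miR-467g, between 6.52 and 6.92 in the other 4 lines, and 6.41 in ESC. The other 4 lines thus also lay above ESC, by less than those 2 lines did. With the fibroblast list as covariate, chosen after the data were seen, the Hox list was still higher than in ESC (camera adjusted p = 5.06e-06). A fit without those 2 lines keeps only 1 pair of lines to give the spread. In this average the fibroblast feeder list was not called, with a median of -0.03 and a camera adjusted p of 0.185. Textbook targets of the miR-15 family, to which miR-15b and miR-322 belong by their shared seed, were not called (median -0.08, camera adjusted p = 0.436). Of 16 members 2 fell and 1 rose (3 fell and 1 rose adjusted over the list alone), and the kinase gene Chek1 fell by 2.75 on the log2 scale (SE 0.62). That call held in only 2 of the 6 fits that left out a line. Chek1 had differences of -2.01 for miR-15b, -3.23 for miR-322 and -3.02 for the lines labelled miR-467g, and only that for miR-322 passed. In the microRNA average 6151 genes had an unadjusted p under 0.05. The count of 3171 genes was 1073 without the first miR-322 line.

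Taken one microRNA at a time, the same kinds of genes stood out against ESC. With limma, 1006 genes were higher and 992 lower in the miR-15b lines, 1274 and 1271 in the miR-322 lines, and 1333 and 1170 in the lines labelled miR-467g. Pou5f1 had differences of -5.68, -6.07 and -6.46 (SE 0.24 each), and Krt8 was higher by 4.52, 4.17 and 3.96 (SE 0.48 each). Gata3 was higher by 2.95, 2.21 and 2.34 (SE 0.44 each) and Hand1 by 3.83, 3.88 and 3.76 (SE 0.75 each). For each microRNA, Gata3 and Hand1 passed in only 2 of the 6 fits that left out a line, with highest adjusted p of 0.102, 0.149 and 0.0835 for Gata3 and 0.180, 0.124 and 0.0863 for Hand1. Cdx2 had differences of 1.35, 0.73 and 0.67 (SE 0.54 each), Eomes of 1.53, 1.01 and 0.64 (SE 0.44 each) and Elf5 of 1.19, 0.70 and 0.78 (SE 0.36 each), none of which passed.

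In the same order of microRNAs, 7, 6 and 5 of 18 TSC core factors rose, and 12, 7 and 7 when adjusted over the list alone (camera adjusted p = 2.50e-07, 0.000447 and 0.000399; adjusted p = 0.598, 0.576 and 0.549 with an estimated correlation). Pluripotency genes fell in 17, 17 and 16 of 27 cases, and 20, 23 and 22 when adjusted over the list alone (camera adjusted p = 1.76e-20, 1.25e-22 and 1.01e-22; adjusted p = 0.407, 0.354 and 0.352 with an estimated correlation). The p53 response had 3, 5 and 5 of 10 genes rising, and 7 rising with 1 falling for each when adjusted over the list alone (camera adjusted p = 0.00777, 0.00424 and 0.00521; adjusted p = 0.598, 0.576 and 0.549 with an estimated correlation). Cell cycle genes were lower as lists with medians of -1.07, -2.03 and -1.92 (camera adjusted p = 0.0233, 3.59e-06 and 7.11e-06; adjusted p = 0.734, 0.576 and 0.549 with an estimated correlation), where 0, 2 and 1 of 19 genes passed with limma and 0 when adjusted over the list alone. The lowest list means were in the first miR-322 line (8.21) and the second line labelled miR-467g (8.16), whose partners had 9.34 and 9.70, near the miR-15b lines at 9.69 and 9.99. Formative and primed epiblast genes fell in 6, 6 and 7 of 12 cases, and 6, 7 and 7 when adjusted over the list alone (camera adjusted p = 6.35e-05, 3.83e-05 and 1.91e-05; adjusted p = 0.439, 0.427 and 0.394 with an estimated correlation).

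Beside these lists the fibroblast feeder list was lower in the miR-15b lines (median -0.67, camera adjusted p = 0.000718; adjusted p = 0.626 with an estimated correlation). In the miR-322 lines and the lines labelled miR-467g it was not called, with medians of 0.28 and 0.21 and a camera test pointing down. Epithelial junction genes were called in the miR-15b lines (camera adjusted p = 0.00638; adjusted p = 0.626 with an estimated correlation), with 4 of 15 rising, also adjusted over the list alone. Their camera adjusted p was 0.278 and 0.295 for the other 2 microRNAs, where 4 of 15 rose as well. Rhox genes were called in the miR-15b lines, with 2 of 8 rising, Rhox9 (5.21, SE 0.60) and Rhox6 (4.26, SE 0.83), and 3 adjusted over the list alone (camera adjusted p = 0.0288; adjusted p = 0.598 with an estimated correlation). The counts of genes fell to 92 for miR-15b without its first line, 16 higher and 76 lower, and to 56 for miR-322 without its first line, 0 higher in limma and 56 lower. Among genes above the median level, 894 were higher and 552 lower for miR-15b, so that the even splits above depended on these choices. For the lines labelled miR-467g the count fell to 542 without either miR-322 line, 192 higher and 350 lower.

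**Figure D2:**
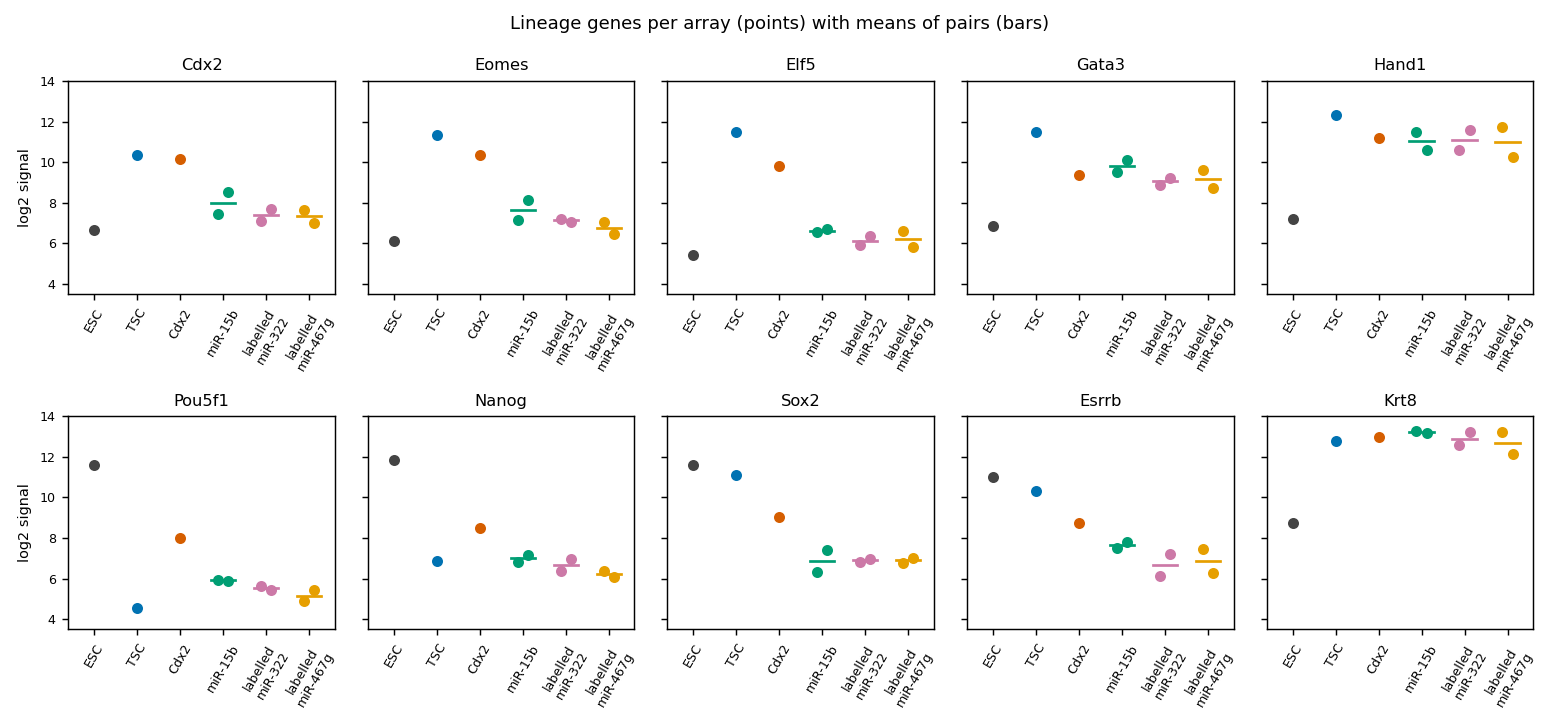
Log2 signal (vertical axis) of 10 lineage genes on each array (points), with bars at the means of pairs of lines and groups along the horizontal axis. Pou5f1 was lower than in ESC by differences of -5.68 to -6.46 in the microRNA groups, while Elf5 was 4.41 above ESC in the Cdx2 line and 0.89 above ESC on average in the microRNA lines.

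To place the induced lines between the references, their differences from ESC were set against those of TSC over the 362 genes called in TSC versus ESC with an absolute log2 difference of 2 or more, of which 171 were higher in TSC and 191 higher in ESC. A slope of 0 stands for ESC and 1 for TSC. The Cdx2 line had a slope of 0.609, and the 6 microRNA lines had 0.598 ± 0.0187 (SD, n = 6), with a range from 0.572 to 0.619. By microRNA the slopes were 0.604 ± 0.0196 for miR-15b, 0.593 ± 0.0110 for miR-322 and 0.595 ± 0.0332 for the lines labelled miR-467g (SD, n = 2). Genes higher in ESC, such as Pou5f1 and Tdgf1, had moved farther toward the TSC level, with a slope of 0.810 ± 0.0165 (SD, n = 6), than genes higher in TSC, such as Elf5 and Eomes, with 0.353 ± 0.0491 (SD, n = 6). In the Cdx2 line these slopes were 0.768 and 0.426. The gap was widest in the first miR-322 line (0.832 and 0.302) and the second line labelled miR-467g (0.823 and 0.283). Both had the highest fibroblast feeder list means of the 6 lines. The other microRNA lines had 0.784 to 0.812 over genes higher in ESC and 0.368 to 0.401 over genes higher in TSC. Of the 362 genes, the percentage moved toward TSC by at least 1 log2 unit was 66.9 ± 2.71 (SD, n = 6) in the microRNA lines and 70.4 in the Cdx2 line. In 100 simulations of lines unchanged from ESC, with TSC kept at its observed differences and the axis genes chosen again, the mean slope was 0.0417, with 0.0442 for genes higher in TSC and 0.0392 for genes higher in ESC, and the percentage moved was 5.42. These simulations assume that the lone arrays vary as the pairs of lines do.

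All these slopes share the lone ESC array, which raises them whatever the cells do. Across genes, which are not independent replicates, the differences from ESC of the microRNA average and of TSC had a covariance of 0.282, against 0.0598 in simulations of unchanged groups with the shared array. For the Cdx2 line the covariance was 0.308 with the same simulated value. Pearson's r was 0.585 for the microRNA average and 0.677 for the Cdx2 line, against 0.655 and 0.50 in these simulations. The simulated groups hold noise alone, so their r is set by the number of arrays. Real differences between groups can bring r below it. A lower r therefore does not show less likeness to TSC than unchanged cells would have. By microRNA, r was 0.642 for miR-15b, 0.512 for miR-322 and 0.545 for the lines labelled miR-467g, against 0.578 simulated for each. The same sign was seen in 64.7% of genes for the average, against 72.7% in simulations, which hold noise alone as well. Of the genes higher in TSC, 392 were also called higher in the microRNA average, and of those lower in TSC, 529 were also called lower. Independent lists of these sizes would share 73.0 and 51.4 genes, a value that leaves out the shared array, and simulated unchanged groups shared 0.0200 and 0 calls on average in limma, a value that leaves out real changes. Part of the excess can therefore come from the shared ESC array, which could not be split. The comparison without a shared array, of the microRNA average minus the Cdx2 line with TSC minus ESC, had r = -0.0719 and a covariance of -0.0268. It asks only whether the microRNA lines lay nearer to TSC than the Cdx2 line did. As the Cdx2 line had itself moved toward TSC, it cannot show whether the microRNA lines resemble TSC. Between the microRNA average and TSC, 27 genes were called in opposite directions from ESC. The shared genes made up 45.4% of the 863 genes higher in TSC and 76.7% of the 690 genes lower in TSC.

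**Figure D3:**
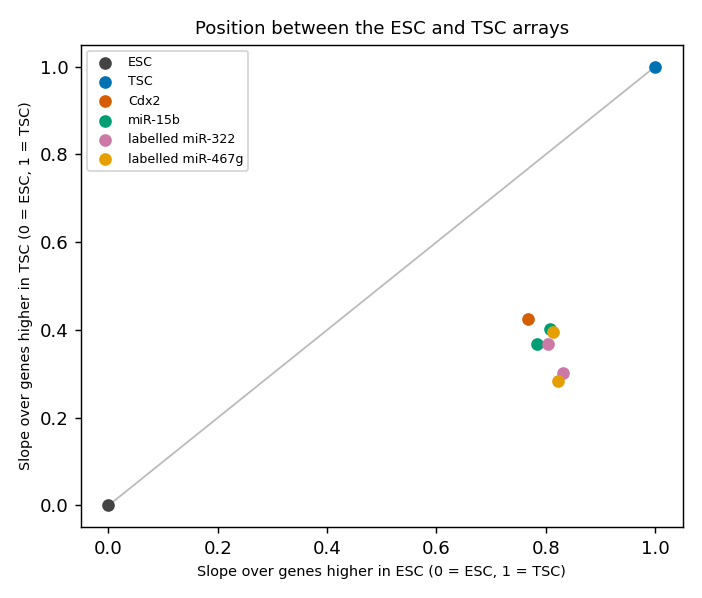
Slope of each array's difference from ESC on that of TSC, over genes higher in ESC (horizontal axis) and genes higher in TSC (vertical axis), without units, with 1 point per array and a line of equal slopes. The 6 microRNA lines averaged 0.810 on the horizontal and 0.353 on the vertical axis.

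Compared with TSC, the microRNA lines lacked much of the expression of the TSC transcription factors, which was the question of how far they remained from the target fate. Elf5 had a difference of -5.18 (SE 0.32, adjusted p = 0.00354), Eomes of -4.18 (SE 0.39), Cdx2 of -2.81 (SE 0.47) and Gata3 of -2.16 (SE 0.39), the last 2 of which passed in only 2 of the 6 fits that left out a line. Sox2 and Esrrb, which TSC share with ESC, were lower by differences of -4.22 (SE 0.39) and -3.28 (SE 0.56). The call of Esrrb also held in only 2 of those 6 fits. The hormone genes Prl7a1 (-4.60, SE 0.14) and Prl3d3 (-4.40, SE 0.14) and the adhesion gene Cdh5 (-4.26, SE 0.21) were lower, whereas the neuropeptide gene Vip (4.34, SE 0.21) and the collagen gene Col10a1 (4.19, SE 0.29) were higher. Mcpt8 (3.48, SE 0.48) and Gzme (3.40, SE 0.61), genes of granule proteases, were also higher, but passed in only 3 and 2 of those 6 fits.

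With limma, 1223 genes were higher and 1368 lower in the microRNA average than in TSC. TSC core factors fell in 7 of 18 cases (9 adjusted over the list alone; median -1.34, camera adjusted p = 0.000266; adjusted p = 0.591 with an estimated correlation), and differentiated trophoblast genes in 5 of 21, also adjusted over the list alone (camera adjusted p = 0.00183; adjusted p = 0.496 with an estimated correlation). Endothelial genes were lower, with 4 of 10 falling (4 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.0147; adjusted p = 0.496 with an estimated correlation), among them Cdh5 and Pecam1 (-2.45, SE 0.25). The fibroblast feeder list was higher (4 of 24 rose, 7 adjusted over the list alone; median 0.98, camera adjusted p = 0.00145; adjusted p = 0.631 with an estimated correlation), including Timp3 (2.26, SE 0.21) and Tagln (1.71, SE 0.27). Beside it, mesenchymal transition genes were higher, with 2 of 12 rising (3 adjusted over the list alone), Cdh2 (1.74, SE 0.35) and Twist1 (1.42, SE 0.27), the latter also a fibroblast list member (camera adjusted p = 0.0300; adjusted p = 0.612 with an estimated correlation).

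Hippo and YAP targets were higher than in TSC with 3 of 8 rising (4 adjusted over the list alone; camera adjusted p = 0.00680; adjusted p = 0.496 with an estimated correlation), Ankrd1 (2.54, SE 0.48), Ccn2 (1.87, SE 0.32) and Ccn1 (1.74, SE 0.16). This list rose with the fibroblast feeder list over the microRNA lines (r = 0.987). Its highest means, 10.65 and 10.57, were in the 2 lines with the highest fibroblast feeder means. The other 4 lines had 9.99 to 10.32, against 9.11 in TSC. The p53 response was higher (4 of 10 rose, 7 adjusted over the list alone; camera adjusted p = 0.00124; adjusted p = 0.496 with an estimated correlation), with Phlda3 (1.24, SE 0.18) and Mdm2 (1.05, SE 0.17). Immune genes were higher (2 rose and 1 fell of 10, and 7 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.0305; adjusted p = 0.496 with an estimated correlation), as were Hox genes (median 0.48, 1 of 37 rose and 0 with limma adjusted over the list alone; camera adjusted p = 0.000295; adjusted p = 0.612 with an estimated correlation). The Hox means, 6.29 in TSC, were highest in the 2 lines with the highest fibroblast feeder means, at 7.28 and 7.34, against 6.52 to 6.92 in the other 4 lines (r = 0.991 between the lists). The Hox list in the microRNA average against TSC had a camera adjusted p of 0.967 with the fibroblast list as covariate. The other 4 lines also lay above TSC, but without both of those lines only 1 pair remains to give the spread. Germline genes were higher as a list (camera adjusted p = 0.0337; adjusted p = 0.612 with an estimated correlation). The 1 of 18 that passed, Rpl10l (2.02, SE 0.43), encodes a ribosomal protein, and 0 passed with limma adjusted over the list alone. Cell cycle genes were lower as a list, with 0 of 19 passing with limma (median -1.31, camera adjusted p = 0.000266; adjusted p = 0.612 with an estimated correlation). Their means, 10.58 in TSC, were lowest in the same 2 lines, at 8.21 and 8.16, against 9.34 to 9.99 in the other 4 lines (r = -0.961 with the fibroblast feeder list). The cell cycle list in the microRNA average against TSC had a camera adjusted p of 0.0582 with that covariate. Here too the other 4 lines lay below TSC, with only 1 pair left when both lines are taken out. Ribosomal protein genes were lower by a median of -0.15 (camera adjusted p = 0.00145; adjusted p = 0.496 with an estimated correlation), while 3 of 57 rose and 2 fell (2 rose and 1 fell adjusted over the list alone). This list also fell as the fibroblast feeder list rose over the microRNA lines (r = -0.974). In this comparison 6630 genes had an unadjusted p under 0.05. The count of 2591 genes fell to 349 without the first miR-322 line.

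In the Cdx2 line compared with TSC, some pluripotency genes were higher and some placental hormone genes lower. Pou5f1 was 10.8-fold higher than in TSC (log2 3.43, SE 0.28, adjusted p = 0.0162), and Dppa1 and Apela, an early embryonic gene and the gene of the ELABELA peptide, were higher by 3.83 (SE 0.39) and 3.79 (SE 0.24). Prl3d3 (-4.45, SE 0.18), Prl7a1 (-4.40, SE 0.18), Cdh5 (-4.08, SE 0.27) and the growth factor gene Bmp4 (-2.33, SE 0.18) were lower. Cdx2 (-0.21, SE 0.62), Eomes (-1.02, SE 0.51) and Elf5 (-1.67, SE 0.42) had differences that did not pass.

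With limma, 126 genes were higher and 285 lower in the Cdx2 line than in TSC. The called lists were TSC core factors (1 of 18 fell, 5 adjusted over the list alone; camera adjusted p = 0.00233; adjusted p = 0.975 with an estimated correlation) and differentiated trophoblast (3 of 21 fell, and 4 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.00229; adjusted p = 0.751 with an estimated correlation). Endothelial genes were also lower (2 of 10 fell, 6 adjusted over the list alone; camera adjusted p = 0.00934; adjusted p = 0.751 with an estimated correlation). Pluripotency genes were higher (3 of 27 rose, and 7 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.0315; adjusted p = 0.975 with an estimated correlation), with Pou5f1 and Tdgf1 (1.73, SE 0.20) among them. This comparison of 2 single arrays had a count of 411 genes that fell to 0 in limma when any one of the miR-15b or miR-322 lines was left out, and 4302 genes had an unadjusted p under 0.05 with all lines.

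The microRNA lines and the Cdx2 line were induced in the same medium, and this comparison set the microRNA transgenes against the lone array of a Cdx2 line. Elf5 and Eomes were lower in the microRNA lines, with differences of -3.51 (SE 0.32, adjusted p = 0.0224) and -3.16 (SE 0.39, adjusted p = 0.0302), and both genes lay below the Cdx2 line in 6 of 6 lines. The difference of Cdx2 itself, -2.60 (SE 0.47, adjusted p = 0.0516), did not pass. The residual pluripotency genes Pou5f1 (-2.45, SE 0.21), Nanog (-1.89, SE 0.26) and Nr0b1 (-2.67, SE 0.14) were lower as well. Col10a1 (4.22, SE 0.29), Vip (3.16, SE 0.21), the intermediate filament gene Nes (2.62, SE 0.45) and the neuronal tubulin gene Tubb3 (1.96, SE 0.31) were higher. Gata3 and Hand1 had differences of 0.00 (SE 0.39) and -0.14 (SE 0.66) that did not pass.

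With limma, 474 genes were higher and 384 lower in the microRNA average than in the Cdx2 line. Pluripotency genes fell in 4 of 27 cases (9 adjusted over the list alone; median -0.60, camera adjusted p = 2.78e-05; adjusted p = 0.779 with an estimated correlation). TSC core factors were not called as a list (camera adjusted p = 0.537), with 2 of 18 falling and 1 rising (3 fell and 2 rose adjusted over the list alone). The fibroblast feeder list was higher with a median of 0.63 (camera adjusted p = 0.0387; adjusted p = 0.961 with an estimated correlation), although 0 of 24 genes rose and 1 fell over all genes, and 0 passed with limma adjusted over the list alone. Moving with it, epithelial junction genes were lower (1 of 15 fell, 2 adjusted over the list alone), Rab25 falling by 2.73 on the log2 scale (SE 0.42), with the same camera adjusted p of 0.0387 (adjusted p = 0.961 with an estimated correlation). Mesenchymal transition genes were higher as a list (camera adjusted p = 0.00476; adjusted p = 0.894 with an estimated correlation), with 0 of 12 passing with limma over all genes and 6 adjusted over the list alone.

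Cell cycle genes were lower than in the Cdx2 line as a list (camera adjusted p = 0.00816; adjusted p = 0.961 with an estimated correlation) and 0 of 19 passing with limma. Ribosomal protein genes were lower (3 of 57 fell, 9 adjusted over the list alone; camera adjusted p = 1.52e-06; adjusted p = 0.779 with an estimated correlation), as were two-cell-like genes (camera adjusted p = 0.0212; adjusted p = 0.894 with an estimated correlation), 0 of 6 passing with limma and 2 adjusted over the list alone. Hippo and YAP targets (camera adjusted p = 0.00468; adjusted p = 0.779 with an estimated correlation; 0 of 8 with limma, 4 adjusted over the list alone), Hox genes (1 of 37 rose, also adjusted over the list alone; camera adjusted p = 0.000461; adjusted p = 0.894 with an estimated correlation) and the p53 response (1 of 10 rose, 5 adjusted over the list alone; camera adjusted p = 0.0219; adjusted p = 0.872 with an estimated correlation) were higher. Over the 6 lines the fibroblast feeder list moved with the cell cycle (r = -0.961), Hox (0.991), Hippo and YAP (0.987), ribosomal protein (-0.974) and p53 response lists (0.819). For the two-cell-like list r was 0.0998. With the fibroblast list as covariate the camera adjusted p of the cell cycle and Hox lists was 0.231 and 0.0119. The lines outside the 2 highest in it also lay below the Cdx2 line in the cell cycle list and above it in the Hox list. Without those 2 lines only 1 pair remains to give the spread. In this comparison 5460 genes had an unadjusted p under 0.05. The count of 858 genes fell to 0 in limma when any one of the miR-15b or miR-322 lines was left out and rose to 2462 without the first line labelled miR-467g. The adjusted p of Elf5 then reached 0.122 at the highest and that of Eomes 0.126.

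No gene passed in the comparisons among the microRNAs, which asked whether the effects depend on the microRNA and on its seed. As the Mir322 signal leaves open which microRNA the lines labelled miR-467g carry, their contrast with the others can be read only as one of labels, not of seeds. The limma F test over the 3 microRNAs called 0 of 19938 genes (1297 at an unadjusted p under 0.05, smallest adjusted p = 0.661). It did not call even the probe set of the induced Mir15b (adjusted p = 0.155 over probe sets), with means of 11.12, 4.31 and 4.04. The lines labelled miR-467g against the others gave 0 genes (369 at an unadjusted p under 0.05, smallest adjusted p = 0.980). Cdx2 (-0.37, SE 0.38), Elf5 (-0.16, SE 0.26), Gata3 (-0.24, SE 0.31), Hand1 (-0.09, SE 0.53) and Sox2 (0.01, SE 0.31) had differences within about one SE, and Eomes (-0.63, SE 0.31), Pou5f1 (-0.58, SE 0.17) and Nanog (-0.58, SE 0.21) did not pass either. The camera test called 12 lists in the lines labelled miR-467g against the others, but only 2 without the second of these lines, and up to 13 without the first miR-322 line. The fibroblast feeder list (median 0.32, camera adjusted p = 7.03e-05), mesenchymal transition (0.42, 0.000816), Hox (0.23, 0.000925) and FGF signalling target lists (0.30, 0.00535) were higher. The TSC core (-0.26, 0.000816), epithelial junction (-0.43, 0.000816), cell cycle (-0.39, 0.000816), germline (-0.29, 5.95e-05), ribosomal protein (-0.08, 5.38e-08), pluripotency (-0.12, 0.0327), DNA methylation (-0.25, 0.0368) and Y-linked lists (-0.20, 0.00535) were lower. In these lists 0 genes passed with limma, and adjusted over the list alone 1 FGF target passed. The adjusted p was 0.633 for each of these 12 lists with an estimated correlation. With the fibroblast feeder list as a covariate, chosen after seeing the data, 3 lists were called and the cell cycle list turned to higher (camera adjusted p = 2.41e-08).

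Whether lines sharing a label were more alike than lines of different labels was left open, because the test by pairings could not pass, and the doubt about the lines labelled miR-467g extends to what their pairing means. After removal of the mean of the 6 lines per gene, paired lines had a mean Pearson correlation across genes of 0.00870, against a mean of -0.173 over all 15 pairs of lines, which the removal of the mean shifts below 0. As many as 4 of the 15 possible pairings had a value as high (exact permutation p = 0.267, one-sided), but the smallest p that 15 pairings allow is 0.0667, so the test could not have passed whatever the data. The highest pairing, at 0.561, joined the miR-15b lines, the first miR-322 line with the second line labelled miR-467g, and the second miR-322 line with the first line labelled miR-467g. The correlation of the first miR-322 line with the second line labelled miR-467g was 0.895, and that of the miR-15b pair was 0.682, the 2 highest of the 15. The miR-322 pair had -0.0128 and the pair labelled miR-467g had -0.643.

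Across the 6 microRNA lines the fibroblast feeder list moved with many other gene groups. Its mean log2 signal was 8.83 and 8.52 in the miR-15b lines, 9.84 and 9.32 in the miR-322 lines and 9.09 and 9.87 in the lines labelled miR-467g, against 9.51 in ESC, 8.34 in TSC and 8.81 in the Cdx2 line. Of 26 relations with other lists computed, 17 had a Benjamini-Hochberg adjusted exact permutation p of Pearson's r under 0.05, 6 positive and 11 negative. These relations are not independent, since the lines differed largely in the same direction. With the mean of the 6 lines removed, the first miR-322 line and the second line labelled miR-467g correlated at 0.895. Each had -0.83 to -0.85 with the miR-15b lines. The permutations also treat the lines as exchangeable, although they come in pairs, and arbitrary gene lists were not tried. The p-values therefore show no tie particular to the fibroblast list. For the TSC core list r was -0.975 (exact permutation p = 0.00139, adjusted p = 0.00516) and the 6 lines had exactly opposite rank orders (Spearman, exact permutation p = 0.00278, adjusted p = 0.00803). Without the 2 lines with the most extreme values, r was -0.956 (the second miR-15b line and the second line labelled miR-467g). For the epithelial junction list, with genes such as Cdh1, Epcam and Krt8, r was -0.946 with the same exact permutation p of 0.00139 and adjusted p of 0.00516, and the rank orders were again opposite with the same p values of 0.00278 and 0.00803. Without those lines r was -0.967. Cell cycle genes had r = -0.961 (exact permutation p = 0.00278, adjusted p = 0.00722), Spearman's rho = -0.943 (exact permutation p = 0.0167, adjusted p = 0.0333) and r = -0.953 without those lines. Hox genes rose with the fibroblast list at r = 0.991 (exact permutation p = 0.00139, adjusted p = 0.00516) with identical rank orders (Spearman, exact permutation p = 0.00278, adjusted p = 0.00803), and r was 0.999 without those lines. The DNA methylation list had r = -0.997 (exact permutation p = 0.00139, adjusted p = 0.00516), and the Hippo and YAP targets had r = 0.987 (exact permutation p = 0.00278, adjusted p = 0.00722). No batch was given in the labels, so these relations could not be computed within batches.

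**Figure D4:**
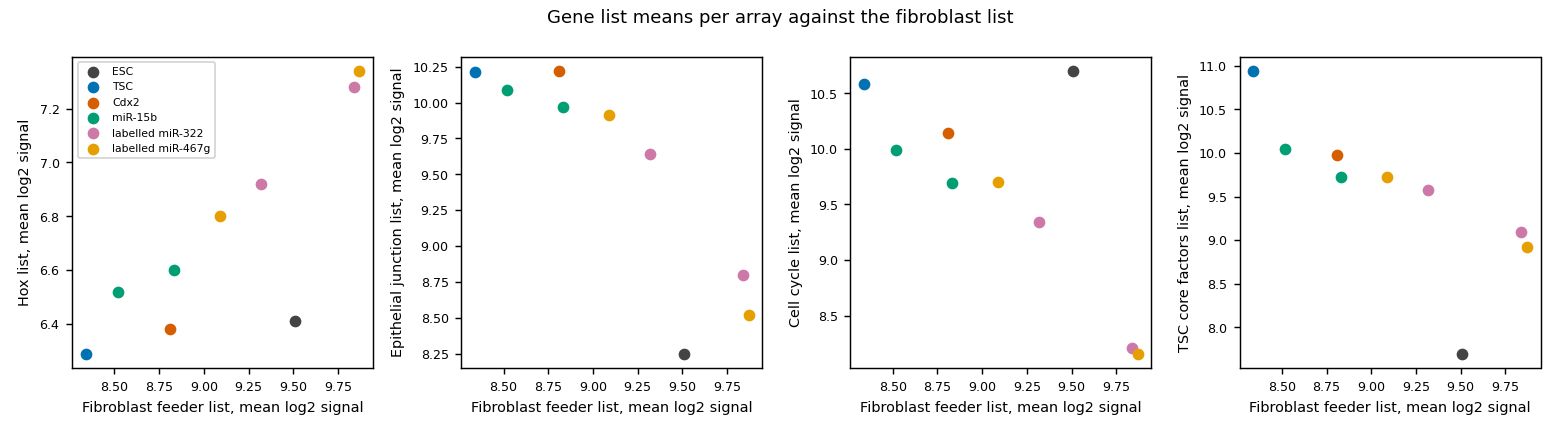
Mean log2 signal of the Hox, epithelial junction, cell cycle and TSC core lists (vertical axes) against that of the fibroblast feeder list (horizontal axis), with 1 point per array coloured by group. Over the 6 microRNA lines r was 0.991, -0.946, -0.961 and -0.975, and ESC, at 9.51 on the horizontal axis, lay off these trends.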

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

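The tests weighed here were chosen after the results were seen, except that of feeder RNA for the 2 lines that stand apart.

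The microRNA lines and the Cdx2 line, induced in the same way, differed in 858 genes by a test of the difference itself, including Elf5 with -3.51 and Eomes with -3.16 (microRNA average minus Cdx2 line, lower in 6 of 6 lines). The count fell to 0 in limma when any one of the miR-15b or miR-322 lines was left out, and Elf5 and Eomes passed in 2 of the 6 such fits, with highest adjusted p of 0.122 and 0.126. The Mir322 probe set, which the comparisons of genes did not use because it carries several symbols, was 7.56 above ESC in the lines labelled miR-467g. Among the 12146 probe sets without a gene symbol, 454 passed in the microRNA average against ESC, 167 higher and 287 lower, and what they measure was not examined.

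The Mir322 probe set was higher in both lines labelled miR-467g than in the lines labelled miR-322, by 2.52 in the mean, a difference that did not pass (adjusted p = 1 in limma) while the lines labelled miR-322 differed by 3.19 from each other. Induction of the cell's own gene cluster was argued against by the other 4 probe sets of that cluster, whose median rise over ESC was 0.55 in the lines labelled miR-467g. RNA of feeder cells was argued against because the 2 lines had a difference of 0 in this probe set, while their fibroblast list means were 9.09 and 9.87. A mislabelled sample or construct remains a candidate explanation, under which these lines could carry the miR-322 transgene. No probe set reads miR-467g itself, and no biological explanation was tested.

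The first miR-322 line and the second line labelled miR-467g stood apart from the other 4 microRNA lines, with a correlation of 0.895 to each other. RNA of feeder cells is a candidate explanation, since of 131 genes raised in the miR-15b lines by 2 or more log2 units 120 were lower in both and 9 higher in both, with a median of -0.76 in the pair with the smaller difference, while 24 of 24 fibroblast list genes were higher in both. Against ESC, also grown on feeders, 18 of the 24 were higher in both lines, such as the brightest probe set, that of Fn1 (13.41 and 13.47 against 12.96), and 6 lower, such as Dcn (7.86 and 8.24 against 10.39) and Lum (4.39 and 4.44 against 6.04). Signals of different probe sets do not measure relative abundance, 20 of the 24 lay above the median of all genes even in TSC, and Fn1 and Twist1 are also mesenchymal transition genes. A change within the induced cells cannot be told apart from RNA of feeder cells. Feeders that divide little or not at all and slowly dividing induced cells would both lower the cell cycle list, whose median was -1.17. A mislabelled sample cannot be told apart either. The 2 lines had a difference of -4.12 in the Mir322 probe set, but the lines sharing the label miR-322 also differed by 3.19.

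Eomes and Elf5 were lower in the microRNA lines than in the Cdx2 line, while the difference of Cdx2, the transgene of that line, did not pass. RNA of feeder cells was argued against as the whole cause by the miR-15b lines, whose fibroblast list means of 8.83 and 8.52 lay on average no higher than that of the Cdx2 line, 8.81, and in which the median of the 2 genes was still -2.95. After quantile normalization the median was -3.37. The deposited values were already normalized between arrays, so this step could move it little and does not decide on normalization as a cause. A chance level of the lone Cdx2 array cannot be told apart from a difference between the transgenes, because the number of Cdx2 arrays was 1. A biological difference between the induced factors stays open and was not tested.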

How the results depend on the processing

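The fibroblast covariate, the removal of both lines that stand apart and the removal of both lines labelled miR-467g were chosen after seeing the data. Quantile normalization, median centring, the mean of probe sets and limma with trend and robust options left every count of genes within 1.5 times the reported one. Under quantile normalization 530 named results kept their direction and side of the threshold, 7 became weaker and 2 stronger, and the median of all genes moved to 0.12 for the microRNA average against TSC. A gene past the threshold in neither setting has no direction to reverse. The cause was not tested unless stated.

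With an estimated correlation, 0 lists were called by camera in limma in each of the 10 comparisons, against 95 calls as reported. Keeping genes above the median level gave 690 genes for TSC against ESC, 404 for Cdx2 against ESC, 1694 for the microRNA average against TSC and 75 for Cdx2 against TSC. It gave 4 lists for TSC against ESC, 7 each for miR-322, for the lines labelled miR-467g and for the microRNA average against ESC, and 6 for the average against Cdx2. Fewer genes were tested. The slopes became 0.575 for miR-15b, 0.539 for miR-322 and 0.541 for the lines labelled miR-467g, and 0.617 for miR-322 over genes with a log2 difference of 3 or more.

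As 1 group, the 6 lines differed from the Cdx2 line in 1586 genes. With a log2 limit of 1 beside the adjusted p, counts were 1142 (miR-15b), 1451 (miR-322), 1382 (labelled miR-467g) and 1457 (average) against ESC, 1127 for the average against TSC and 408 against Cdx2, since the limit removes genes by construction. With that limit and no test, 1733 genes stood out for Cdx2 against ESC, 1249 for Cdx2 against TSC, 1290 for the average against Cdx2 and 15 for the lines labelled miR-467g against the others. Fits of only the groups compared gave 927 genes for miR-15b and 0 in limma for miR-322 and the lines labelled miR-467g, with 1 residual degree of freedom. Such fits gave no value for 2 lone arrays.

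With the fibroblast covariate, counts rose to 4060 (TSC against ESC), 4211 (Cdx2 against ESC), 5384 (miR-15b), 7270 (miR-322), 7437 (labelled miR-467g) and 7884 (average against ESC), to 3783 for Cdx2 against TSC and to 3709 for the average against Cdx2, as the median residual SD fell from 0.133 to 0.0925. The called lists became 10 for Cdx2 against ESC, 10 for Cdx2 against TSC and 3 for the lines labelled miR-467g against the others. Reversed were Gata4 in Cdx2 against ESC, to -0.66, Tfap2c in the average against Cdx2, to 0.55, and the cell cycle list in the lines labelled miR-467g against the others (camera adjusted p = 2.41e-08). Without both lines that stand apart, 315 genes were called for TSC against ESC, 927 for miR-15b, and 0 in limma for Cdx2 against ESC, for miR-322 and the lines labelled miR-467g against ESC, for the average against TSC and Cdx2, and for Cdx2 against TSC. The fit then had 1 pair left. Lists were 11 for Cdx2 against ESC, 16 for miR-15b and 3 for the lines labelled miR-467g against the others. Without the lines labelled miR-467g, 4030 genes were called for miR-322.

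Leaving out 1 line at a time gave 370 to 2098 genes for TSC against ESC, 24 to 1355 for Cdx2 against ESC, 92 to 2806 for miR-15b, 56 to 4030 for miR-322, 542 to 3862 for the lines labelled miR-467g and 1073 to 4616 for the average against ESC. It gave 349 to 4609 for the average against TSC, 0 to 538 in limma for Cdx2 against TSC and 0 to 2462 for the average against Cdx2. The highest count of each came without a line labelled miR-467g, and the remaining line was assumed to vary like the other pairs. For the lines labelled miR-467g against the others, 2 to 13 lists were called. Of the named called genes, those that stayed called in all 6 such fits were 24 of 56 (TSC against ESC), 7 of 38 (Cdx2 against ESC), 12 of 56 (miR-15b), 9 of 55 (miR-322), 25 of 52 (labelled miR-467g), 35 of 65 (average against ESC), 25 of 64 (average against TSC), 0 of 28 (Cdx2 against TSC) and 0 of 26 (average against Cdx2), all in limma. Without either miR-322 line the share of higher genes fell to 0% for Cdx2 against ESC, and without the first of them to 0% for miR-322. The test of likeness could not pass the threshold under any alternative, since the smallest p that 15 pairings allow is 0.0667. The seed match test was not run. Signals near the background of the arrays limit dim genes, and the filter on them changed the share of higher genes to 65.8% for TSC against ESC, 61.8% for miR-15b and 65.9% for the average against Cdx2.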

Other observations

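The limb genes in this part were chosen after their values were seen, and the lists had been written before the data were examined.

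In the first miR-322 line and the second line labelled miR-467g, 6 genes known from limb mesenchyme and picked after their values were seen were higher than in the other line of each pair, without a test. Hoxd13, a regulator of digits, was higher by 1.05 and 1.44, Tbx5, a regulator of the forelimb, by 0.97 and 1.47, and the limb growth factor gene Fgf10 by 1.16 and 1.93. Over the same pairs, 24 of 24 fibroblast feeder genes were higher as well (medians 0.52 and 0.75), and the Hox list rose with that list over the 6 lines at r = 0.991. Sema3a was higher by 1.02 and 1.88, Tbx18 by 1.15 and 1.31, and Hoxa13 by 0.54 and 0.81. In ESC, Hoxd13 and Tbx5 had signals of 7.67 and 6.52, against 9.97 and 8.67 in the second line labelled miR-467g.

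In the microRNA average against ESC, Igf2, a growth factor gene expressed from the paternal allele, was higher by 3.33 (SE 0.28), and Sfmbt2, whose introns hold the miR-467 cluster, by 2.35 (SE 0.55). Rhox9 and Rhox6, X-linked homeobox genes of placenta and germline, were higher by 4.85 (SE 0.53) and 3.79 (SE 0.73). The calls of Sfmbt2 and Rhox6 held in only 2 of the 6 fits that left out a line, and those of Igf2 and Rhox9 in all 6. Igf2, Sfmbt2, Rhox9 and Rhox6 also differed from ESC by 2.94, 2.78, 4.61 and 3.65 in the Cdx2 line, which has no microRNA transgene. In TSC these differences were 3.31, 3.07, 5.18 and 4.36. Sfmbt2 and Rhox6 did not pass in either. Of 22 imprinted genes 5 rose and 1 fell, and the list was not called (median 0.73, camera adjusted p = 0.134). The Rhox list had a camera adjusted p of 0.0863.

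Of the 27 lists, 7 were called in none of the 10 comparisons with camera. Their smallest adjusted p was 0.244 for extraembryonic endoderm, 0.0537 for mesoderm, 0.0593 for neural ectoderm, 0.116 for cardiac muscle, 0.0629 for imprinted genes, 0.25 for miR-15 family targets and 0.327 for the response to histone deacetylase inhibitors. In the last list, written because valproic acid was added, 0 of 8 genes passed with limma in the microRNA average against ESC (median 0.38, camera adjusted p = 0.677). Medians, means and tests of the neural ectoderm and FGF target lists differed in sign in that comparison.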
